A study of Mus musculus with 8 samples.

How the data were processed

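RNA from cultured mouse hippocampal neurons was measured on 8 Affymetrix arrays, 4 from untreated cultures and 4 from cultures held in 55 mM KCl for 4 h, and each sample was placed in its group by its title. Labelling followed the Affymetrix WT Plus kit, per the labels' protocols. The deposited values are log2 probe set values from the authors: RMA, which corrects background, normalizes between arrays and summarises the probes of a probe set, and the Partek software are named in the submitters' processing notes, with no version, order or settings. Whether the authors applied a batch adjustment is not given in the sources used here. RMA values are relative to the set of arrays processed together and compress differences near background, so fold changes of dim genes are understated and a low value does not show that a transcript is absent. The scanner files were not analysed here, and signal over background could therefore not be assessed probe by probe.

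Probe sets were named from the platform annotation supplied with the series. Of 34472 probe sets, 23521 had 1 gene symbol, 1814 had several and 9137 were unnamed here. No gene was named from a probe set with several symbols. For the 1082 genes with several probe sets, the probe set with the highest mean over all 8 arrays was used, which left 22180 genes. Of these, 21994 had an identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols differed there. Because the build behind the array annotation is not given, no coordinates are reported. No 2 arrays had the same values throughout, and 0 columns belonged to other samples.

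The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the single term, two-sided), with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Standard errors of log2 changes are the moderated ones. Gene lists were tested with camera from limma, which sets a list's change against that of all other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 36 lists, 9 of them cell type markers. Members of a list were also adjusted over the list alone, and 4 listed symbols were replaced by their current names. Some genes stand in more than 1 list. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule takes the Gadd45 family, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap (leaving out predicted and clone names), and, for each described list, up to 4 members with the smallest p. It named 68 genes, of which 47 passed the threshold. A further 8, said to be chosen after their values were seen, were added. For lists that are not described in full, only members past the threshold are named.

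The titles give both groups the replicate numbers 1 to 4, while the mouse numbers all differ. Whether the numbers pair the arrays was checked from the correlation, across genes, of the arrays' deviations from their group means. It was 0.64, 0.23, 0.41 and 0.37 for the 4 same-numbered pairs, all over 0.1, and all 8 arrays correlated best with the array of their own number in the other group, with 0.3 the highest value of any other pair. The numbers were therefore taken to pair the arrays, although the labels name no shared litter or day, and a fit with the replicate number as a block was run beside the planned fit without it. Its median standard error was 0.119, against 0.142 without the block. The mean log2 change over all genes was -0.01.

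The fits were tested on simulated data with the observed means and spreads. In 10 simulations of the untreated against KCl comparison over 22180 genes, each with 200 changed genes, 70.2% of genes with a log2 change of 1 and 93.1% of those with a change of 2 were recovered, and 6.26% of the calls were false. Camera found 10 of 10 lists shifted by 0.5 and called 1 of 350 unshifted lists. Simulated genes were drawn independently, with no correlation between genes and no structure by replicate number. These rates therefore do not show how the fits or camera perform where real genes or same-numbered arrays move together. Alternatives fixed before the data were examined were the replicate block, quantile normalization repeated, centring on array medians, genes brighter than the median gene, the mean of all probe sets of a gene, all probe sets, trended and robust eBayes, a linear model without moderation, array weights, a minimum change of 1.5-fold, leaving out each array in turn, an estimated inter-gene correlation and fry. Fits without both arrays numbered 1, with and without the block, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.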

Results

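Hippocampal neurons of C57BL/6J mice, a common inbred laboratory strain, were taken from late-stage embryos and kept for 11 days in vitro. RNA was then measured on Affymetrix whole-transcript arrays, which report the brightness of short DNA probes grouped into probe sets. The 8 arrays fell into 2 groups: 4 cultures were untreated and 4 had been held in 55 mM KCl for 4 h. Raised extracellular potassium depolarises neurons and opens voltage-gated calcium channels, and it is widely used in culture as a stand-in for electrical activity. The labels gave each array a mouse number of its own. Each array held 34472 probe sets, with medians of 4.44 to 4.48 on the log2 scale, and the precision of what follows is limited by the number of arrays. Expression over 22180 named genes correlated at r = 0.959 to 0.988 between arrays of a group and at 0.949 to 0.979 between arrays of different groups, across genes. The first principal component took 36.6% of the variance and set both arrays numbered 1 apart, at scores of -48.6 and -43.2. The second took 27.1% and separated the KCl arrays from the untreated ones.

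**Figure D1:**
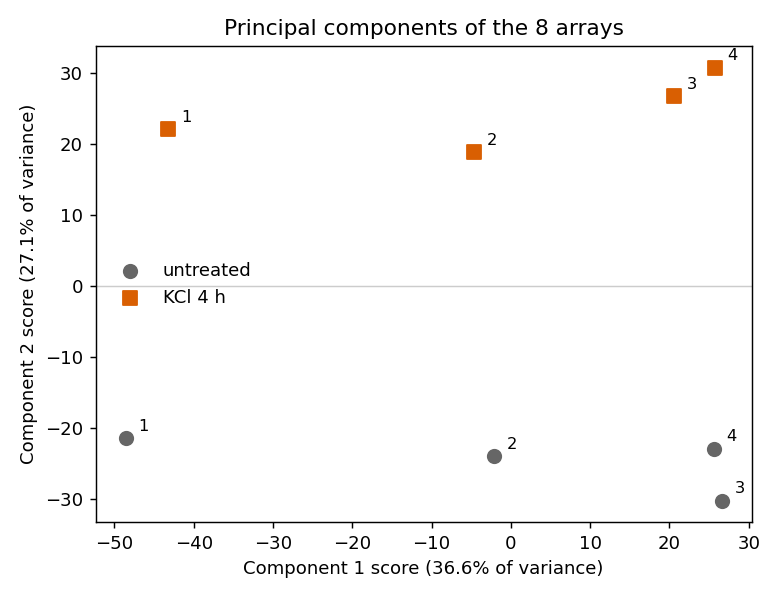
Scores of the 8 arrays on the first principal component (x axis, 36.6% of the variance) and the second (y axis, 27.1%), computed from log2 values of 22180 genes and numbered by replicate. The untreated arrays (grey circles) lie between -30.2 and -21.4 on the second component and the KCl arrays (orange squares) between 18.8 and 30.7.

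The series title concerns transcription of the Gadd45 family, small stress-inducible nuclear proteins linked to DNA repair and active DNA demethylation, under neuronal activity. After 4 h of KCl, Gadd45g (probe set 17287361) rose 9.92-fold, from a log2 value of 5.55 ± 0.651 to 8.86 ± 0.277 (SD, n = 4 each). Gadd45b (probe set 17235511) rose 4.81-fold, from 6.456 ± 0.730 to 8.723 ± 0.549 (SD, n = 4 each). Both were higher after KCl in 4 of 4 same-numbered pairs. Gadd45a had no probe set of its own: probe set 17467316 is annotated to Gadd45a and to the transcript E230016M11Rik, so its signal cannot be given to either. That probe set stood at 5.95 ± 0.25 in untreated and 6.23 ± 0.26 in KCl arrays (SD, n = 4 each), a log2 difference of 0.28 that did not pass the test although 4 of 4 pairs were higher (adjusted p = 0.64, with values of 0.44 to 0.87 when single arrays were left out).

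The log2 change was 3.31 (SE 0.305, adjusted p = 0.00201) for Gadd45g and 2.27 (SE 0.39, adjusted p = 0.0238) for Gadd45b. Gadd45g passed the threshold with any single array left out. The call of Gadd45b was lost without KCl replicate 2 (adjusted p = 0.057), KCl replicate 3 (0.078) or untreated replicate 2 (0.075), 3 (0.073) or 4 (0.066), with log2 changes of 2.1 to 2.31 in those fits. The fits with an array left out had no replicate block. With the block and all arrays, the SE of Gadd45b was 0.179 (limma adjusted p = 0.00297). The untreated array numbered 1 had the highest Gadd45b value of its group, 7.54 against 5.95 to 6.21 in the other 3, and without both arrays numbered 1 the log2 change of Gadd45b was 2.4 (adjusted p = 0.0042).

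**Figure D2:**
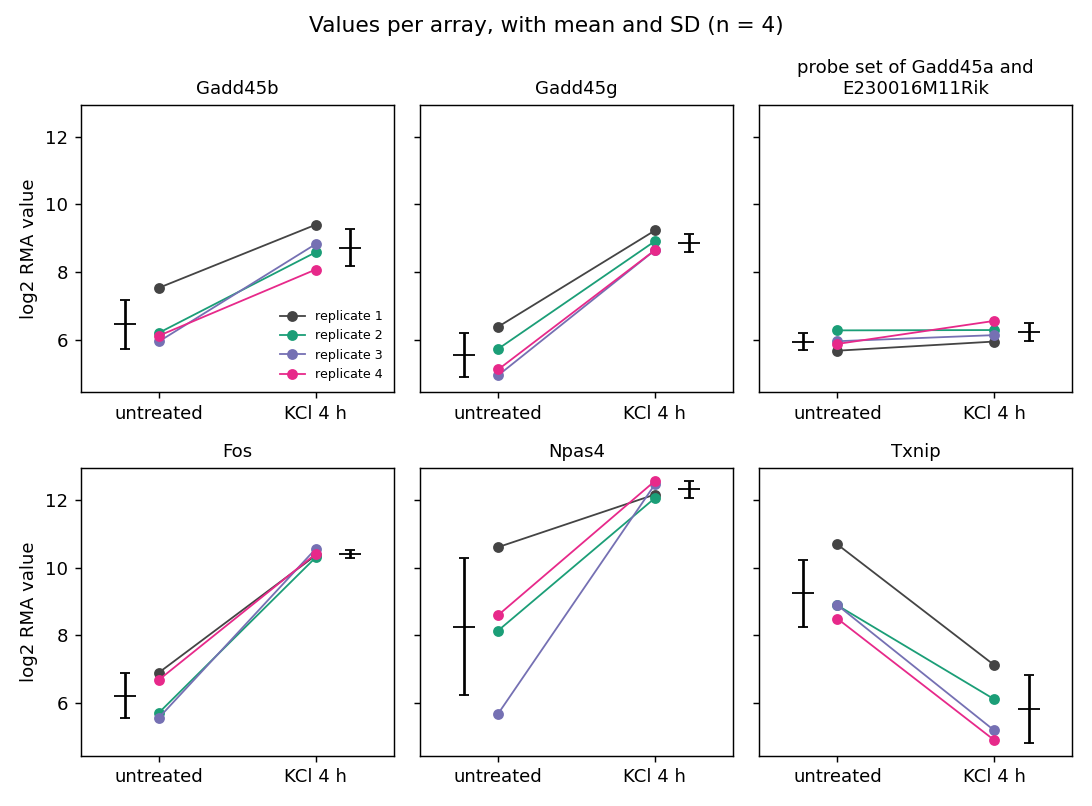
Values per array for Gadd45b, Gadd45g, the probe set shared by Gadd45a and E230016M11Rik, Fos, Npas4 and Txnip, with log2 RMA values on the y axis and the 2 groups on the x axis. Lines join arrays of the same replicate number, and the black marks give each group's mean and SD (n = 4). Npas4 ranged from 5.69 to 10.61 in untreated arrays and from 12.06 to 12.56 in KCl arrays.

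Across the transcriptome, 297 genes rose and 227 fell after 4 h of KCl, of 22180 tested, at an adjusted p under 0.05. The 10 largest rises were led by transcription factors of the AP-1 and nuclear receptor 4A families: Fosb rose 43-fold, Fos 18.2-fold, Nr4a1 16.2-fold and Nr4a2 14.9-fold. They were followed by Nfil3, a leucine zipper repressor tied to the circadian clock (10.2-fold), then Gadd45g, the stress-response factor Atf3 (8.73-fold), the zinc finger factor Klf4 (8.58-fold), the AP-1 member Junb (7.29-fold) and Spty2d1, a histone chaperone (6.79-fold). The largest fall was that of Txnip, the thioredoxin-interacting protein that restrains glucose uptake, from 9.239 ± 0.982 to 5.835 ± 1.002 (SD, n = 4 each), a fold of 0.0945. The other 9 of the 10 largest falls were the zinc finger genes Zfp759 (log2 change -2.30), Zfp39 (-2.02), Zfp518a (-1.79) and Zkscan16 (-1.61), the microtubule adaptor Hook1 (-2.07), the intraflagellar transport gene Ttc21b (-1.81), Ankrd49 (-1.64), the cilia-associated Cfap97 (-1.56) and Trmt1l (-1.51).

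A change of at least 2-fold was seen for 182 of the genes that rose and 77 of those that fell. The KCl arrays lay entirely beyond the untreated arrays for 8.16% of all genes, against 2.86% expected by chance if the arrays are unpaired. With the replicate number as a block, 539 genes rose and 446 fell, and 490 genes passed in the same direction in both fits. The total of 524 fell to 186 without KCl replicate 3, 246 without KCl replicate 4, 259 without untreated replicate 2, 236 without untreated replicate 3 and 332 without untreated replicate 4. The genes that rose then numbered 118, 159, 152, 156 and 189 in the same order, and those that fell 68, 87, 107, 80 and 143, with 144 falling without KCl replicate 2. Without both arrays numbered 1, a fit added after the data were seen, 249 genes rose and 216 fell, and 323 of the 465 were also called with all arrays. Among the 20 genes of largest change, the calls of Atf3 (adjusted p = 0.052 without KCl replicate 3), Txnip (0.058 to 0.082 without KCl replicate 2, 3 or 4 or untreated replicate 2 or 3), Zfp759 (up to 0.082), Zkscan16 (up to 0.094) and Cfap97 (up to 0.062) were lost in fits with single arrays left out. For Zfp759 and Zkscan16 these were the fits without KCl replicate 1, 3 or 4 or untreated replicate 2, 3 or 4. For Cfap97 they were those without untreated replicate 2, 3 or 4. Without KCl replicate 2, Cfap97 passed at an adjusted p of 0.05 after rounding. With the replicate block and all arrays, the limma adjusted p was 0.0045 for Atf3, 0.000879 for Txnip, 0.0253 for Zfp759, 0.0212 for Zkscan16 and 0.0292 for Cfap97. A second probe set of Zfp39 had a log2 change of -0.07. In a comparison chosen after the falls were seen, the median log2 change was -0.3 over 259 Zfp genes with another Zfp gene within 1 Mb in assembly GRCm38.p6 and -0.083 over 110 without.

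Genes that neurons switch on within minutes to hours of activity were taken as 2 lists. Of 34 measured rapid immediate-early genes, 21 rose, none fell and 13 did not pass the test. Beside Fos, Fosb, Junb, Klf4, Nr4a1, Nr4a2 and Atf3, the transcription factor Egr4 rose 4.85-fold, from 5.532 ± 0.326 to 7.81 ± 0.027 (SD, n = 4 each, adjusted p = 0.00046). Of 27 measured late-response genes, 6 rose, 1 fell and 20 did not pass. Among these, Tiparp, a mono-ADP-ribosyltransferase, rose 5.19-fold, Ptgs2, which encodes cyclooxygenase-2, rose 5.5-fold, and the chromatin remodeller subunit Baz1a rose 4.84-fold, while Rasgrp1, a guanine nucleotide exchange factor for Ras, fell to 0.506 of its untreated level.

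Adjusted over the list alone, 29 rapid genes rose, and 11 late-response genes rose and 1 fell. The mean log2 change was 1.91 over the rapid list and 0.60 over the late-response list, and both lists moved against all other genes (camera adjusted p = 3.34e-43 and 3.33e-07). The rapid list also passed with an estimated correlation (adjusted p = 0.016, but 0.34 when the replicate block was added), whereas the late-response list did not (adjusted p = 0.37). Without both arrays numbered 1, 23 rapid genes rose, and 6 late-response genes rose and 1 fell. Without KCl replicate 3 the calls of Ptgs2 (adjusted p = 0.054) and Rasgrp1 (0.053) were lost, and that of Baz1a was lost without KCl replicate 3 (0.064) or untreated replicate 3 (0.065) or 4 (0.056). A second probe set of Tiparp had a log2 change of 0.03.

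Npas4, Arc and Bdnf, which are textbook activity genes, were chosen after their values were seen. The neuron-specific factor Npas4 had a log2 change of 4.05 with an SE of 0.856 and missed the threshold (adjusted p = 0.0517, 0.0324 with the replicate block). Its untreated values were 10.61, 8.14, 5.69 and 8.60, and without untreated replicate 1 or 3 its adjusted p was 0.012 or 0.046. It was 0.022 with array weights and 0.022 among brighter genes. The synaptic gene Arc stood at 6.322 ± 0.492 and 7.886 ± 0.773 (SD, n = 4 each, adjusted p = 0.0915) and the neurotrophin Bdnf at 6.25 ± 0.431 and 7.419 ± 0.846 (adjusted p = 0.235). Without KCl replicate 2, Arc (adjusted p = 0.024) and Bdnf (0.033) passed, and Arc did among brighter genes (0.048).

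**Figure D3:**
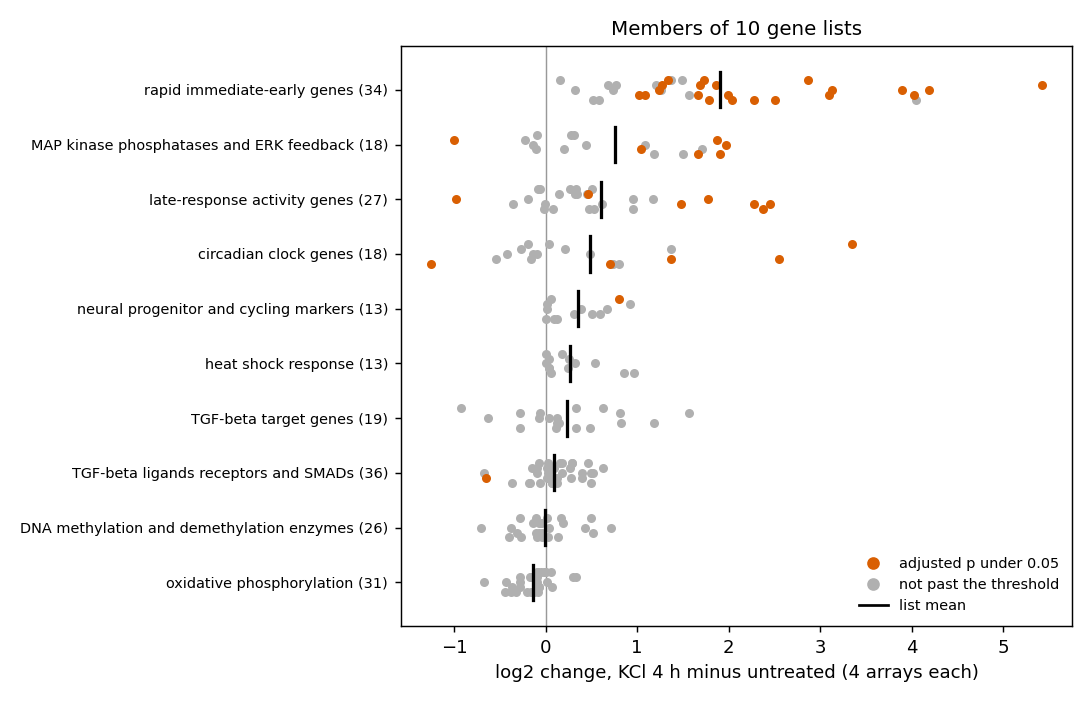
Log2 change after 4 h of KCl (x axis, KCl minus untreated, 4 arrays each) of every measured member of 10 gene lists fixed before the data were examined, with the number measured in parentheses. Each dot is a gene, orange where its adjusted p over all genes was under 0.05, and the black bar is the list mean, which runs from -0.14 for oxidative phosphorylation to 1.91 for the rapid immediate-early genes.

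Phosphatases and adaptors that switch off MAP kinase signalling, the cascade through which calcium reaches many activity genes, mostly rose where they moved. Of 18 measured members, 5 rose, 1 fell and 12 did not pass. Dusp16 rose 3.66-fold, Dusp1 3.17-fold, the EGF receptor inhibitor Errfi1 3.76-fold and Dusp14 3.93-fold. The fifth to rise, Dusp10 (2.06-fold), and the 1 that fell, Dusp7 (0.497 of its untreated level), lay outside the naming rule and were chosen after their values were seen. Among 18 circadian clock genes, 4 rose, 1 fell and 13 did not pass. Nfil3 rose as given above, the nuclear receptor Rorb rose 5.86-fold (5.487 ± 0.409 to 8.039 ± 0.259, SD, n = 4 each) and the repressor Cry2 rose 2.59-fold, while Npas2, a partner of the core clock factor Arntl, fell to 0.421 of its untreated level. Arntl itself, also chosen after its values were seen, rose 1.63-fold.

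Adjusted over the list alone, 8 of the MAP kinase feedback genes rose and 1 fell, and 5 of the clock genes rose and 1 fell. The mean log2 change was 0.76 over the first list (camera adjusted p = 8.85e-06) and 0.48 over the clock genes (adjusted p = 0.0156), and neither passed with an estimated correlation (adjusted p = 0.27 and 0.52). Without both arrays numbered 1, 3 MAP kinase feedback genes rose and none fell, and 4 clock genes rose and 1 fell. The list call of the clock genes was lost without KCl replicate 1 (adjusted p = 0.066) or 2 (0.065) or untreated replicate 3 (0.067) or 4 (0.082). In single-array fits the call of Errfi1 was lost without KCl replicate 3 (adjusted p = 0.053). That of Dusp14 was lost without KCl replicate 1, 3 or 4 or untreated replicate 2 or 3 (up to 0.076), and that of Arntl without KCl replicate 2 or 3 or untreated replicate 2 or 4 (up to 0.07). Dusp10 passed in 2 of the 8 such fits, those without KCl replicate 2 or untreated replicate 4, and Dusp7 in 2, those without untreated replicate 1 or 4. With the replicate block the adjusted p of Dusp7 was 0.05.

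The title also names TGFβ signalling. The list called ligands, receptors and SMADs here spans the wider family, with activin and BMP members such as Bmpr1a and secreted antagonists such as Fst. Of its 36 measured genes, Acvr1b, an activin type I receptor, fell to 0.638 of its untreated level (log2 change -0.65, SE 0.121, adjusted p = 0.0317). None rose and 35 did not pass. The next smallest p-values in that list were those of the secreted antagonist Fst (log2 change 0.47, adjusted p = 0.182), the inhibitory Smad7 (0.62, adjusted p = 0.212) and the receptor Bmpr1a (0.50, adjusted p = 0.247). None of 19 measured TGFβ target genes passed, with Klf10 at -0.92, Pmepa1 at 0.82 and the SMAD corepressor Skil at 0.82. The design text names DNA methylation, which was not measured on these arrays. None of 26 measured enzymes and readers of DNA methylation passed over all genes, and the smallest p-values were those of the glycosylase Mbd4 (log2 change 0.49, adjusted p = 0.13), the nuclease subunit Ercc4 (-0.71, 0.132), the 5-methylcytosine oxidase Tet2 (0.52, 0.158) and the methyl-binding protein Mbd2 (0.43, 0.163).

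Adjusted over the list alone, 1 of the ligands, receptors and SMADs fell and none rose, and none of the target genes or methylation genes passed. At an unadjusted limma p under 0.05 there were 4 of 19 target genes and 6 of 26 methylation genes, against 2888 of all 22180 genes. As lists, the ligands, receptors and SMADs (mean log2 change 0.09, camera adjusted p = 0.286), the target genes (0.23, adjusted p = 0.158) and the methylation genes (-0.01, adjusted p = 0.991) did not pass. Camera tests a shared shift up or down. With fry run for changes in either direction, the p, not adjusted over lists, was 0.12, 0.19 and 0.0068 in the same order. A small p of that kind can rest on few members. With the replicate block, the target list passed with camera (adjusted p = 0.034, but 0.42 with the block and an estimated correlation). So did 2 of its members chosen after their values were seen, the matricellular genes Ccn2 (log2 change 1.19, adjusted p = 0.0173) and Thbs1 (1.57, 0.046), and the receptor Bmpr1a (adjusted p = 0.0474). The target list averaged 6.40 to 6.86 in arrays numbered 1 and 2 and 5.56 to 5.94 in those numbered 3 and 4. In the same order, Thbs1 stood at 9.01 to 10.27 and at 4.25 to 7.16. Its SE was 1.428 without the block and 0.315 with it, and that of Ccn2 was 0.652 and 0.166. The target list also passed without untreated replicate 1 (adjusted p = 0.0065) or KCl replicate 3 (0.039), but its adjusted p with an estimated correlation and all arrays was 0.99, and a second probe set of Ccn2 had a log2 change of -0.03. Acvr1b passed in 1 of the 8 fits with an array left out, that without untreated replicate 1, with adjusted p up to 0.095, and no gene of its list passed without both arrays numbered 1. In single-array fits Mbd2 (adjusted p = 0.047) and Ercc4 (0.04) passed without KCl replicate 2.

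Lists for stress, energy metabolism and progenitor cells passed with the preset correlation but not with an estimated one. The heat shock list lay higher after KCl (camera adjusted p = 0.0156, but 0.37 with an estimated correlation) although none of its 13 measured genes passed over all genes, with the inducible chaperone Hspa1b at 1.96-fold, Hspa4l at 1.46-fold, the co-chaperone Bag3 at 1.81-fold and Hspa4 at 1.18-fold. The 31 measured genes of oxidative phosphorylation lay lower as a list (camera adjusted p = 0.0333, but 0.99 with an estimated correlation), again with no single gene past the threshold: the complex I subunit Ndufb5 had a log2 change of -0.43, the ATP synthase subunits Atp5c1 and Atp5pb -0.67 and -0.38, and the complex III subunit Cyc1 -0.37. Among 13 markers of neural progenitors and cycling cells, Pcna, the DNA polymerase clamp, rose 1.75-fold (adjusted p = 0.0191) and 12 did not pass. The cell-cycle kinase Cdk1 stood at 1.6-fold (adjusted p = 0.176), the survivin gene Birc5 at 1.24-fold (0.475) and Pax6 at 1.89-fold (0.545). The culture medium held AraC, which kills dividing cells, per the labels.

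The mean log2 change was 0.27 for heat shock, -0.14 for oxidative phosphorylation and 0.35 for the progenitor and cycling markers (camera adjusted p = 0.0156, but 0.37 with an estimated correlation). With fry, which tests a list on its own, none of the 3 passed (adjusted p = 0.16, 0.55 and 0.15), and the other 4 lists that passed with camera did (up to 0.049). Among brighter genes the calls of the progenitor markers (adjusted p = 0.1) and oxidative phosphorylation (0.32) were lost, and that of oxidative phosphorylation also with trended and robust eBayes (0.056). Adjusted over the list alone, 2 heat shock genes and 1 progenitor marker rose and no oxidative phosphorylation gene passed. At an unadjusted limma p under 0.05 there were 3 of 13 heat shock and 4 of 31 oxidative phosphorylation genes, against 2888 of all 22180 genes. With the replicate block, Hspa1b (adjusted p = 0.0339), Bag3 (0.047) and Pax6 (0.0461) passed. Leaving out single arrays also ended the heat shock call (adjusted p = 0.088 without KCl replicate 3, 0.09 without untreated replicate 2) and the progenitor call (0.053 without KCl replicate 2, 0.063 without KCl replicate 3, 0.082 without untreated replicate 4). It ended the oxidative phosphorylation call without KCl replicate 1 (0.051) or 4 (0.3) or untreated replicate 1 (0.05) or 3 (0.29), and that list also missed the threshold without both arrays numbered 1 (0.074). Without those arrays 2 progenitor markers rose, the other being Cdk1 (adjusted p = 0.025), which also passed without KCl replicate 1 alone (0.015). Pcna was lost without KCl replicate 2, 3 or 4 or untreated replicate 4 (adjusted p up to 0.067), and Hspa1b passed without untreated replicate 3 (0.038).

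Further lists covered the synapse and ion channels, stress and signalling, metabolism and cell type markers. Over 7 lists of glutamate and GABA receptor subunits, voltage-gated channels, release proteins and postsynaptic scaffolds, 3 of 151 measured genes rose, 1 fell and 147 did not pass. The scaffold gene Homer1, also a late-response gene, rose 2.79-fold, the GABA receptor subunit Gabrg1 rose 1.77-fold and the potassium channel Kcnh8 rose 1.43-fold, while the silent potassium channel subunit Kcnv1 fell to 0.442 of its untreated level. Over 6 lists for p53 targets, the unfolded protein response, oxidative stress, apoptosis, interferon and NF-kB, 5 of 117 genes rose and 1 fell. The chaperone Dnajb9 rose 2.14-fold, the phosphatase adaptor Ppp1r15a 2.82-fold, the antiproliferative Btg2 3.22-fold and the survival factor Mcl1 1.83-fold, with Ptgs2 as given above, and the interferon signalling factor Stat2 fell to 0.428 of its untreated level. Over 5 further lists, for cholesterol synthesis, glycolysis, neuropeptides, histone acetylation and cytosolic ribosomal proteins, the hexokinase gene Hk2 (1.56-fold) and the acetyltransferase gene Crebbp (1.39-fold) rose and 115 of 117 genes did not pass. Over the 8 lists of markers for neurons, glia, vessels and meninges, 1 of 86 genes changed, the astrocyte glutamate transporter Slc1a2, which fell to 0.583 of its untreated level.

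None of these 26 lists passed as a list, with camera adjusted p from 0.111 to 0.991. Camera tests a shared shift up or down and can miss a list whose members move both ways. With fry run for changes in either direction, the p, not adjusted over lists, ran from 1.3e-07 for the potassium channels to 0.99 for the microglia markers. It was 3.2e-06 for the unfolded protein response and 4.2e-05 for cholesterol synthesis. Such a p can rest on few members and does not show that a list moved as a set. Of these 3 lists in the same order, 29 of 31, 22 of 24 and 18 of 18 genes did not pass over all genes. Adjusted over the list alone, 4 synaptic and channel genes rose and 1 fell, 10 genes of the 6 stress and signalling lists rose and 3 fell, 4 genes of the 5 further lists rose and 1 fell, and 2 markers fell. With the replicate block the p53 target list passed (adjusted p = 0.019, but 0.42 with the block and an estimated correlation), 11 of the 117 genes of the 6 stress and signalling lists rose and 3 fell, and the call of Slc1a2 was lost (adjusted p = 0.062). The p53 list also passed with array weights (adjusted p = 0.042) and without KCl replicate 4 (0.012) or untreated replicate 1 (0.0065) or 2 (0.05 after rounding), the NF-kB list without KCl replicate 4 (0.025), and the sodium and calcium channel list without untreated replicate 1 (0.037). Without both arrays numbered 1 and with the block, the p53 list passed too (camera adjusted p = 0.0096). With an estimated correlation and all arrays, the adjusted p of each of these 3 lists was 0.99. Kcnv1, Dnajb9, Ppp1r15a and Mcl1 passed with any single array left out, although a second probe set of Mcl1 had a log2 change of 0.35 against 0.87, while Stat2 was lost without KCl replicate 3 (0.054) or 4 (0.051), and Hk2 passed in 2 of the 8 fits, those without KCl replicate 2 or untreated replicate 4. Homer1 passed only without KCl replicate 1, Gabrg1 only without KCl replicate 2, Slc1a2 only without untreated replicate 2, Btg2 and Crebbp only without untreated replicate 1, and Kcnh8 in none of the 8, with adjusted p up to 0.14. Both arrays numbered 1 lay on the same side of all other 6 arrays in 4 of 9 marker lists, and in the other 5 they did not. Astrocyte markers averaged 8.61 and 8.42 in the untreated and KCl arrays numbered 1 against 7.69 to 8.17 in the other 6, fibroblast and meningeal markers 5.00 and 4.87 against 4.17 to 4.72, inhibitory neuron markers 5.50 and 5.65 against 5.93 to 6.44 and pan-neuronal markers 9.75 and 9.83 against 10.05 to 10.20. Endothelial and mural markers averaged 5.09 to 5.19 in arrays numbered 1 and 2 and 4.43 to 4.57 in those numbered 3 and 4. Fibroblast and meningeal markers averaged 4.68 to 5.00 and 4.17 to 4.30 in the same order. Over 18 markers of ciliated cells, a list made after the data were seen, the arrays numbered 1 exceeded the other arrays of their group by a median of 1.85 log2 units in both groups.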

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

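The tests of a label swap and of saturation were chosen after the results were seen. Each group of 4 values of a named gene or described list was checked for a lone array far from the other 3. Of 172 groups, 7 had one, fewer than the 5% that chance gives, and 4 of the 7 lay in arrays numbered 1.

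Activity genes were uneven among the untreated arrays. In untreated replicate 1, Atf3 stood at 6.45 against 4.70 to 4.87 in the other 3 and Gadd45b at 7.54 against 5.95 to 6.21, and Npas4 spanned 5.69 to 10.61 over the untreated arrays. A swap of labels between the groups is argued against, since the mean of the rapid immediate-early genes in every KCl array exceeded that of every untreated array, by at least 1.41 log2 units. Saturation of Npas4 in the untreated arrays is argued against as well, because each of its untreated values lay at least 1.45 log2 units below every KCl value of the same probe set. These values were known when the comparison was chosen, so it describes them and is no independent test. In the KCl arrays Npas4 stood at 12.06 to 12.56 and the brightest gene at 13.96 to 14.02. A higher starting level of the whole rapid list in untreated replicate 1 cannot be told apart from ordinary spread: without Npas4 its list mean lay 0.29 above the next untreated array, less than the range of 0.46 among the other 3, and no biological explanation was tested.

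Among the genes of DNA methylation, Tet2 was lowest in untreated replicate 1, at 8.24 against 8.61 to 8.62. The receptor Bmpr1a reached 9.52 in KCl replicate 1 against 8.99 to 9.07, and Acvr1b stood at 7.54 in KCl replicate 2 against 7.86 to 7.91. Btg2 was 8.62 in KCl replicate 3 against 8.93 to 8.99, and Hspa4 was 10.54 in untreated replicate 3 against 10.14 to 10.17. Of the 10951 probe sets that were unnamed here or carried several symbols, and so entered no comparison of genes, 62 were higher after KCl and 47 lower in a fit of all probe sets (limma adjusted p under 0.05).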

How the results depend on the processing

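The fits without both arrays numbered 1 were chosen after the data were seen; the other settings were planned. The total of 524 genes, 297 higher and 227 lower, moved over 1.5 times with the replicate block (985, 539 and 446) and with a linear model without moderation (129, 89 and 40). Trended and robust eBayes gave 150 lower and, in all, 430 genes, of which 65.1% were higher against 56.7%. Quantile normalization and median centring left 57.2% and 58.4% higher. Leaving out single arrays gave 186 to 501 genes in all, 118 to 254 higher and 68 to 247 lower, with the fewest without KCl replicate 3 and the most without untreated replicate 1. Fewer arrays lower the power of each such fit, and the cause of the differences between them was not tested. Gadd45b ranged from 2.04 to 2.63 and lost its call in 5 of the 8 such fits, Gadd45g from 3.11 to 3.59, and probe set 17467316 from 0.17 to 0.39. Of 50 named genes past the threshold, 26 passed with any single array left out, 41 under all 6 of quantile normalization, median centring, brighter genes (48 of the 50 tested), the mean of probe sets, trended and robust eBayes and array weights, and 49 with the block; in these fits 0 reversed. The 9 that lost a call in those 6 were Acvr1b, Btg2, Crebbp, Dusp7, Gabrg1, Hk2, Homer1, Kcnh8 and Slc1a2 (adjusted p of 0.05 to 0.078). Without both arrays numbered 1, 39 of the 50 kept their call, and 39 did so with the block added. Losses outside those 9 in the fit without the block were Arntl (limma adjusted p = 0.076), Dusp10 (0.087), Errfi1 (0.052) and Zkscan16 (0.064). Relative to all genes, the rapid list ranged from 1.77 to 2.06 and the late-response list from 0.53 to 0.72, and the latter lost its call with an estimated correlation (0.613, adjusted p = 0.37; the construction allows for genes that move together). The TGFβ target list (0.244) gained a call with the block (adjusted p = 0.034) and without both arrays numbered 1 with the block (0.295, adjusted p = 0.031), with a range of 0.069 to 0.47, and the ligands, receptors and SMADs ranged from 0 to 0.19 with no call. The direction of the camera test of the near-zero DNA methylation list (mean -0.005) reversed among brighter genes (0.036) and in 3 fits with an array left out (means -0.005, 0.002 and 0.03; range -0.038 to 0.03), none past the threshold; the mean kept its sign in the first of the 3 and changed it without untreated replicate 2 (0.004), and the cause was not tested. With an estimated correlation 1 of the 7 lists kept its call, and with the block added 0 did. With the block 9 lists passed. The block changed no call of a named gene or list beyond those given beside the results. Signal over background, which limits dim genes, was not analysed here.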

Other observations

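The tests of symbol families, gene span, and cell type and normalization in the arrays numbered 1 were chosen after the results were seen. Genes were grouped by the stem of their symbol, and 109 families of at least 20 measured genes were set against all other genes with camera, of which 7 passed. None of the 7 passed with an estimated correlation. Counts at an unadjusted limma p under 0.05 are to be set against 2888 of all 22180 genes. With the replicate block the same 7 passed and so did Tmem (adjusted p = 0.043), Myo (0.035), Arhgap (0.027) and Dusp (0.034), none of them with an estimated correlation without the block (0.48 to 0.65). The median log2 change was -0.267 over 28 Mrps genes, for mitochondrial ribosomal proteins of the small subunit (none past the limma threshold, 3 at an unadjusted p under 0.05, family adjusted p = 7e-04, but 0.61 with an estimated correlation), and -0.173 over 43 Mrpl genes, for those of the large subunit (2 lower, adjusted p = 0.0011, but 0.65). It was -0.411 over 23 Zdhhc genes, most of which encode palmitoyltransferases (3 lower, adjusted p = 0.00065, but 0.48 with an estimated correlation), and, for transcription factor families, -0.161 over 37 Zbtb genes (4 lower, 1 higher, adjusted p = 0.013, but 0.61) and -0.175 over 21 Gtf genes (none past the limma threshold, 8 at an unadjusted p under 0.05, adjusted p = 0.028, but 0.71). Over 21 Stk genes, which encode kinases of several kinds, the median was 0.102 (1 higher, adjusted p = 0.028, but 0.65 with an estimated correlation). These directions, and that of the Zfp genes, held under quantile normalization and median centring, and Stk did not pass without both arrays numbered 1 (adjusted p = 0.16).

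Genes that rose had longer spans than the median gene. The median genomic span, from the RefSeq table of GRCm38.p6, was 36.1 kb for 280 protein-coding genes that rose against 18.7 kb for all 18964 measured, with a permutation p of 1e-04, the smallest that 10000 permutations over genes can give. For 211 genes that fell it was 22.3 kb (permutation p = 0.1). The permuted sets were drawn from all measured protein-coding genes and were not matched on signal. A difference in span between bright and dim genes therefore cannot be told apart from a link of span with the response to KCl.

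Zinc finger genes stood out among the falls: of 370 measured Zfp genes, 33 fell and 2 rose, with a median log2 change of -0.243 (camera adjusted p = 3.7e-11 over the 109 families, adjusted p = 0.48 with an estimated correlation). Low signal of their probe sets is argued against, as 10000 lists of other genes matched on signal had medians of -0.066 to -0.006 (2.5th to 97.5th percentile). So is an effect of a single array pair, since the median was below 0 in 4 of 4 same-numbered pairs (-0.091, -0.207, -0.386 and -0.357). Cross-hybridisation between neighbouring paralogs stays open. The 110 Zfp genes with no other Zfp gene within 1 Mb had a median of -0.083, inside the matched range of -0.092 to 0.02. Only 4.65% of the matched lists were as low, and 6 of the 110 fell and 1 rose. A fall of these genes is thus neither shown nor excluded. Of 259 with a neighbour, 27 fell and 1 rose. Their median was -0.3 (difference -0.217, permutation p = 1e-04, the smallest 10000 permutations can give). The permutation took genes as independent, and neighbours that move together would make its p too small. A shared response of clustered Zfp genes to KCl is a candidate explanation too and was not tested.

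Both arrays numbered 1, which stand apart on the first principal component, had higher levels of genes of motile cilia. Over 18 measured of 21 listed ciliated-cell markers, the median excess over the other arrays of the same group was 1.85 log2 units in each group, with 14 and 16 markers over 1. The brightest were Rsph4a (9.7 against 8.13 in the other 6 arrays), Spag6l (9.37 against 7.52) and Tppp3 (8.84 against 6.38), and the ciliogenesis factor Foxj1 stood at 7.77 against 5.48. The list was made after the data were seen, so the excess of its markers over other genes is no independent test. Other genes of like brightness were not raised as sets. Over 10000 signal-matched lists of 18, medians were -0.254 to 0.253 in the untreated and -0.163 to 0.303 in the KCl group (2.5th to 97.5th percentile). Genes dimmer than the median gene had median differences of 0.009 and -0.022 in the same order. These values argue against normalization or array quality that moves genes of like brightness alike. Effects of array quality on particular genes were not tested. Ciliated cells in the cultures numbered 1 are a candidate source that stays open, though 13 of the 18 markers lay above the median gene in the other 6 arrays as well, 0 of them stand in a fixed list, and no biological difference between replicate numbers is named by the design. Signal over background was not assessed, so a place above the median gene does not show expression. The dim markers Mcidas (4.18 against 4.29 in the other 6 arrays) and Ccno (3.99 against 4.14) were not raised in the arrays numbered 1.

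Chance can be excluded as the source of the count of changed genes only if the arrays are taken as unpaired: of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 524 genes. The highest other, 196, set the arrays numbered 1 and 2 against those numbered 3 and 4, which points to a structure by replicate number. If the numbers pair the arrays, the comparison is with the 8 splits that part all 4 same-numbered pairs, too few for a share under 5%, and the highest other among them gave 0 genes. The other splits keep at least 1 pair together.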
